A study of Mus musculus with 2 samples.

How the data were processed

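H3K27me3 ChIP-seq of mouse limb at embryonic day 13.5 was given as peak lists for 2 biological replicates of 1 group, each with 2 technical replicates combined per the file headers and text deposited beside the lists. Group and replicate numbers were taken from the labels. The replicates have separate biosample entries, but the number of embryos behind each is not given in the sources used here.

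The 4 lists are in narrowPeak format on the assembly mm10, per the deposited text. Peaks of the replicate lists were called per replicate, the pooled list on both replicates together, and the replicated list was derived by the authors from the pooled and the replicate lists. The aligner, the peak caller, their versions and the thresholds are not given in the sources used here. The deposited text names different numbers of input files for the 2 replicate lists, without stating their roles, so whether both were made against the same control is not known. Control libraries were not analysed here. Each peak has, as deposited, a display score, a signal value with an unstated scale, a −log10 p and a −log10 q by the authors' peak caller, and the offset of its summit. The lowest −log10 p in the deposited lists was 2.03, and in the replicate 1 list 28.8% of peaks had a −log10 q under 2, against 2.75% in the replicated list. The lists are therefore permissive, and weak peaks are many. Narrow peaks split broad domains of this mark into pieces, which is why bases and merged domains were compared as well as peaks. Of the replicated peaks 59.9% overlapped peaks of both replicate lists by the rule below. Read depth per sample is unknown, since the lists hold no read counts. Precision is given as the SD between the 2 replicates, which at n = 2 is itself imprecise, and as exact binomial intervals at the 95% level for shares of genes, which cover counting error only.

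Coordinates were used with the GRCm38 reference sequence and the GENCODE M21 annotation, which are on the same build; chromosome names matched and the last peak of each list lay within each chromosome. Peaks on chromosomes 1 to 19 and X were used, which left out 1 peak of replicate 1 and 2 pooled peaks. Printed coordinates are 1-based. The promoter of a protein-coding gene was the window of 2 kb on each side of the gene's annotated 5' end, for 21755 genes; 196 genes on Y and the mitochondrial genome were left out. Genes were matched by symbol, and 54 share theirs with another gene. A promoter was called marked when the replicated list covered at least 25% of the window. Values per gene are the percent of the window covered in each replicate list, as mean ± SD (n = 2). The gene's 5' end can be that of a rare upstream transcript, so the start of the lowest-numbered transcript was tried too. Peaks were called shared when they overlapped by at least 50% of the shorter one.

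Overlap of replicates was tested against 1000 circular shifts of 1 list along each chromosome (200 for the shared bases and for alternatives), and the location of covered bases in promoters, exons, introns and intergenic sequence in the same way. Intervals that crossed a chromosome end after a shift were dropped. The 19 gene lists and 20 gene families, the naming rule and all tests were fixed before the data were examined, except where stated. Of the listed imprinted genes H19 and Meg3 are non-coding and were not tested. Marked genes of a list were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists or over the families. Because neighbouring genes share domains, this p is too small for clustered genes, and each list and family was also set against 10000 random lists matched on deciles of promoter CpG observed/expected and 10000 rotations of the marks along the gene order. The Hox subgroups were compared by an exact permutation test in place of the random resampling first planned, because 1 group has fewer than 10 genes. Its p is the share of all splits with as large an absolute difference in means. X was ranked among 20 chromosomes by percent covered. Replicated peaks were merged over gaps of at most 3 kb, and domains of at least 10 kb were called broad.

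Genes are named by a rule: per list and family up to 4 marked members with the highest mean coverage and 3 unmarked with the lowest, the genes starting in the 15 broadest domains, the gene nearest to each of the 10 peaks with the highest signal value, the 5 genes on each side with the largest difference between replicates, and the Hox genes. The other unmarked limb regulators, and the genes in the closing section, were chosen after their values were seen.

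Alternatives were each replicate list alone, peaks with a −log10 q of at least 2, the pooled list, windows of 1 and 5 kb, any overlap or at least 50% coverage, any transcript start, other overlap rules, equal numbers of peaks, G+C content, and other merging gaps and widths. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The code was tested on simulated data: promoter coverage differed from that of bedtools 2.31.1 by 0 percentage points over 1000 windows, and an overlap share of 59.9% was recovered as 59.9%. Of simulated lists of 25 genes without a difference 1.25% had a Fisher p under 0.05, and of those with a marking probability of 0.5 per gene 93.5% did. Marks were simulated independently per gene, so these rates do not cover neighbouring genes that share marks. The overlap check used copies of peaks moved slightly, so it tests the code alone.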

Results

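Trimethylation of histone H3 at lysine 27 (H3K27me3), the mark deposited by Polycomb repressive complex 2, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in limbs of C57BL/6-strain mouse embryos at embryonic day 13.5. The limbs came from embryos of both sexes. The peaks are of limb tissue and not of single cell types, so they do not show which cells carried the mark. The series held 1 group of 2 biological replicates, so no contrast between conditions was possible and the comparisons were between replicates, gene groups and genome regions. The authors deposited a peak list for each replicate, a list called on the pooled reads, and a replicated list that is a subset of the pooled one. The lists held 119287 peaks for replicate 1, 84994 for replicate 2, 165888 for the pooled reads and 65664 in the replicated list. Peaks covered 56.4 Mb in replicate 1, 44.7 Mb in replicate 2 and 62.2 Mb in the replicated list, which was 2.14%, 1.70% and 2.36% of chromosomes 1 to 19 and X. The read depth behind each list is unknown, because a peak list holds no read counts.

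The first comparison asked how far the replicates shared their marked regions. Of the replicate 1 peaks, 37.6% overlapped a replicate 2 peak by at least 50% of the shorter peak, and of the replicate 2 peaks 54.7% overlapped one of replicate 1. Lists shifted at random along the chromosomes gave on average 2.25% and 3.04%, and none of 1000 shifts reached the observed shares (one-sided permutation p = 0.001 for each, the smallest the shifts can give). The replicates shared 44.5% of the bases that either covered, against 1.03% on average after shifting. Sharing was most frequent among the strongest peaks. In the top decile by the deposited signal value, 95% of the replicate 1 peaks and 98.1% of the replicate 2 peaks were shared, against 15.9% and 41.8% in the bottom decile. For replicate 2 the lowest share was 36.0%, in decile 2. Peaks of the top decile were also wider, with medians of 1189 bp and 1482 bp against 221 bp and 229 bp. A wide peak meets this overlap rule more easily, so strength and width cannot be told apart here. On X the balance differed, since 51.7% of the replicate 1 peaks but 27.1% of the replicate 2 peaks were shared.

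**Figure D1:**
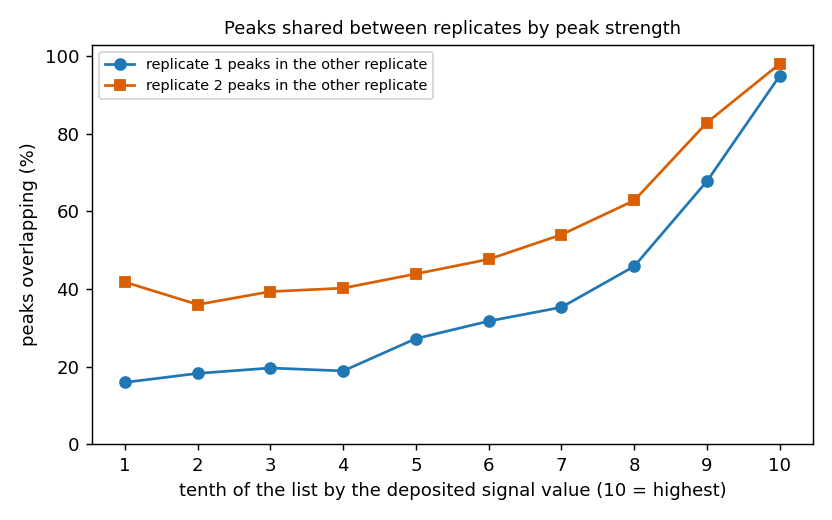
Share of each replicate's peaks (y axis, %) that overlap a peak of the other replicate, by decile of the deposited signal value within the list (x axis, 10 is the highest); circles are replicate 1 and squares replicate 2. The share reaches 95% and 98.1% in the highest decile.

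The authors' replicated list kept 39.6% of the pooled peaks and 70.1% of their bases. Kept peaks had a median width of 539 bp, against 234 bp for those left out. Of the kept peaks, 39350 overlapped peaks of both replicate lists by at least 50% of the shorter peak, 13461 overlapped those of replicate 1 alone, 9490 those of replicate 2 alone and 3363 neither list. No pooled peak that overlapped both replicate lists was left out.

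At the level of promoters, taken as 2 kb on each side of the annotated 5' end, the replicates were much closer. The replicated list covered at least 25% of the promoter of 3799 of 21755 protein-coding genes (17.5%), called marked here. Its peaks are those called on the pooled reads, so a marked promoter need not reach 25% in either replicate list. Hoxa13, for example, was marked with 17.55% covered in replicate 1 and 21.3% in replicate 2. Only 3534 promoters reached 25% in at least 1 replicate list. The list of replicate 1 marked 3377 promoters and that of replicate 2 marked 3231, of which 3074 were common, 303 were in replicate 1 alone and 157 in replicate 2 alone. These common promoters were 87.0% of those marked in either list (95% exact binomial confidence interval 85.8% to 88.1%, which treats genes as independent). Across genes, which are not independent replicates, the covered percentages had Pearson's r = 0.979 and Spearman's rho = 0.882. On autosomes the common share was 88.6%, and on X it was 57.0%, with 75 promoters marked in replicate 2 alone and 2 in replicate 1 alone.

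The regulators of other organs carried the mark almost without exception. All 56 listed transcription factors of the nervous system were marked, among them the neural determinants Neurod2, Six3, Pax6 and Neurog2, whose promoters were covered to 100% ± 0 (SD, n = 2). All 19 regulators of heart, kidney and gonad were marked, including Foxl2 and Hand1 (both 100% ± 0, SD, n = 2), Foxf1 (98.4% ± 2.25, SD, n = 2) and Tcf21 (95.7% ± 1.41, SD, n = 2). Of the 27 endoderm regulators 25 were marked, led by Cdx2, Foxa2, Mnx1 and Gata5, all at 100% ± 0 (SD, n = 2). The exceptions were the hepatic factors Hnf4a (1.84% ± 2.6, SD, n = 2) and Hnf1a (6.83% ± 6.12, SD, n = 2). Each of these 3 shares exceeded that of the other protein-coding genes, 17.2% to 17.4%, with Benjamini-Hochberg adjusted p over the 19 lists of 4.91e-42, 1.46e-14 and 2.45e-16 (Fisher's exact test, two-sided). Their shares in both replicate lists lay between 88.9% and 100%.

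Regulators used in the limb itself were divided. Of 38 transcription factors of limb mesenchyme, 29 were marked (76.3%; adjusted p = 1.46e-14, Fisher's exact test against other genes). Marked members with high coverage included Irx3 (96.6% ± 2.93, SD, n = 2), Alx4 (90.4% ± 0.159, SD, n = 2), Alx1 (88.9% ± 5.89, SD, n = 2) and the hindlimb determinant Pitx1 (84.9% ± 0.442, SD, n = 2). The forelimb factor Tbx5 was covered to 69.8% ± 13.4 (SD, n = 2). The 9 unmarked members were Prrx1, Prrx2, Gli1, Gli2, Gli3, Hand2, Twist1, Etv5 and Pbx1. No peak of either replicate touched the promoters of Prrx1, Prrx2, Gli2, Gli3 and Pbx1. Set against the regulators of the 3 other organ groups together, of which 100 of 102 were marked (98.0%), the limb regulators were marked less often (odds ratio 0.0644, p = 0.000131, Fisher's exact test, two-sided).

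Among 24 ligands, receptors and antagonists of limb patterning, 17 were marked (70.8%, adjusted p = 3.40e-08, Fisher's exact test). In each replicate list the share was lower, at 58.3%. Shh, the signal of the posterior limb margin, and Wnt7a, the dorsal ectodermal signal, were covered to 100% ± 0 (SD, n = 2), Fgf17 to 98.9% ± 1.56 and Wnt3 to 98.8% ± 1.68 (SD, n = 2). Fgf10, the mesenchymal signal to the apical ridge, Fgfr1 and Ptch2 had no peak at their promoters in either replicate.

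The Hox genes differed by cluster. All 19 genes of the HoxB and HoxC clusters were marked, and their promoters were covered to 94.7% on average (SD of the replicate means 0.104, n = 2). The 9 posterior genes of HoxA and HoxD, which pattern the limb axis, averaged 23.5% (SD of the replicate means 0.385, n = 2). This difference of -71.1 percentage points gave p = 1.45e-07 in an exact permutation test over genes, two-sided, which treats genes of 1 cluster as independent although they share domains. In the posterior HoxA group, Hoxa9 and Hoxa11 had no peak at their promoters in either replicate, Hoxa10 was covered to 7.26% ± 1.40 and Hoxa13 to 19.4% ± 2.65 (SD, n = 2). Posterior HoxD genes ranged from 22.1% ± 7.02 at Hoxd13 to 65.9% ± 16.5 at Hoxd12 (SD, n = 2). The 11 anterior and central genes of HoxA and HoxD averaged 58% (SD of the replicate means 0.206, n = 2), from 2.38% ± 3.36 at Hoxa7 to 99.8% ± 0.336 at Hoxd1 (SD, n = 2). Hoxd3 and Hoxd4 have nearly the same annotated 5' end, so 1 window counts for both genes. Hoxa3 was covered to 26.6% at its annotated 5' end but to 69.8% at the most covered of its transcript starts.

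**Figure D2:**
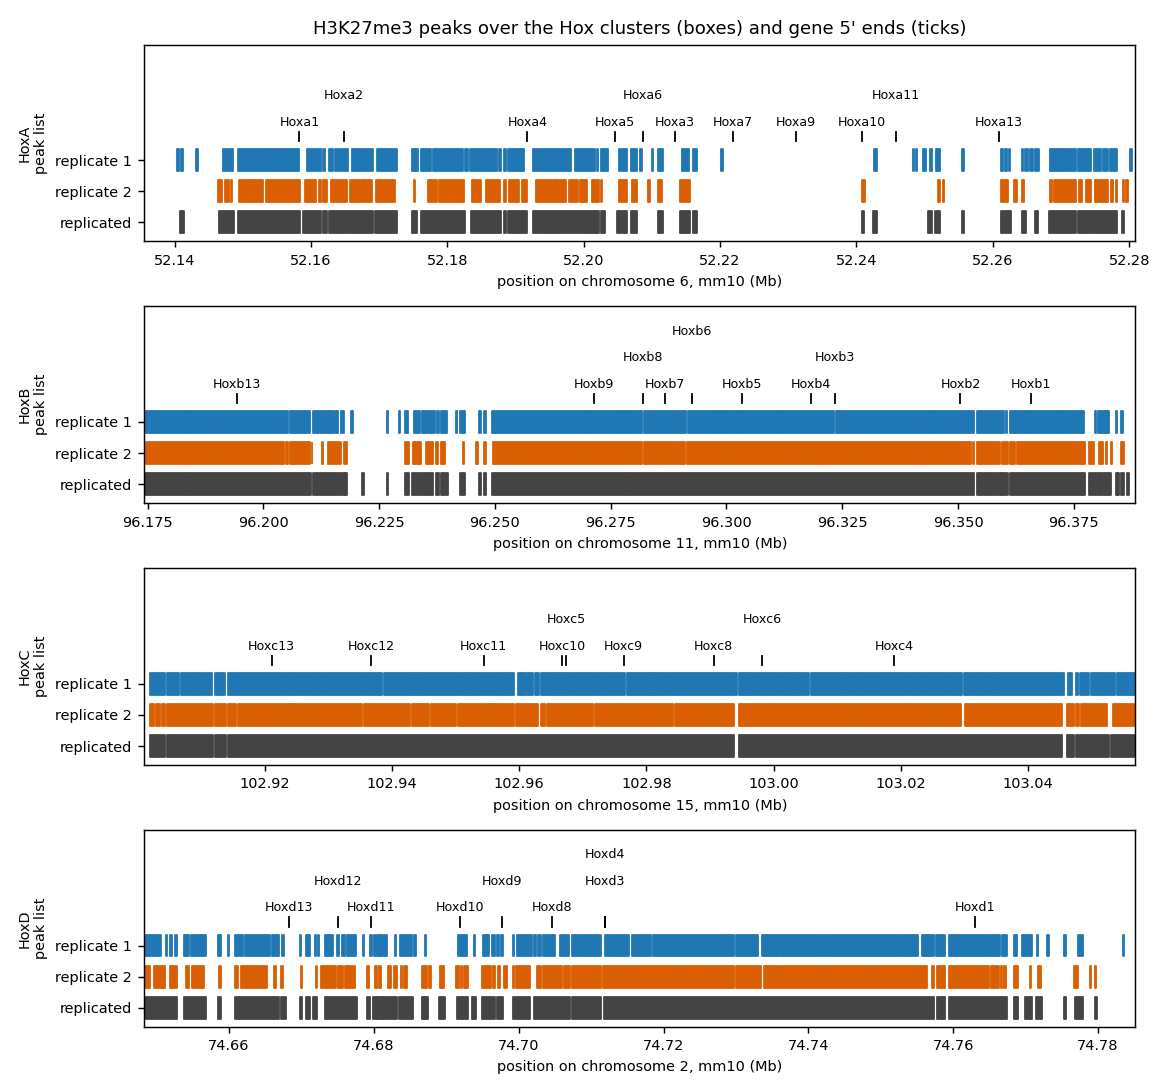
Peaks of replicate 1, replicate 2 and the replicated list (boxes, 1 row per list) over the HoxA, HoxB, HoxC and HoxD clusters, with the 5' end of each gene as a tick; the x axis is the position in Mb on mm10. HoxC is covered nearly throughout, and HoxA has few peaks from Hoxa7 to Hoxa11.

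Over the whole clusters in mm10, peaks of the replicates covered 35.9% ± 4.73 of HoxA (chromosome 6, 52155590 to 52260880), 79.5% ± 2.37 of HoxB (chromosome 11, 96194316 to 96368256), 92.5% ± 0.982 of HoxC (chromosome 15, 102921103 to 103036852) and 72.2% ± 0.946 of HoxD (chromosome 2, 74668310 to 74765142) (SD, n = 2). In the replicated list 6 of the 9 posterior HoxA and HoxD genes were marked (adjusted p = 0.00278, Fisher's exact test), all 19 HoxB and HoxC genes (adjusted p = 1.46e-14) and 9 of the 11 anterior genes (adjusted p = 1.39e-05). Fisher's test counts neighbouring genes of 1 domain as independent. Against marks rotated along the gene order the adjusted permutation p was 0.0241 (posterior), 0.000543 (HoxB and HoxC) and 0.000950 (anterior). The unmarked anterior genes were Hoxa6 and Hoxa7. The call for the posterior genes rested on replicate 1, since with the list of replicate 2 alone 33.3% of them were marked (adjusted p = 0.164, Fisher's exact test).

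Genes of the tissues that make up the limb were also marked more often than other genes, though in which cells of the limb is not known. Of 25 skeletal genes 11 were marked (44.0%; adjusted p = 0.00314, Fisher's exact test), including Ihh, the signal of growth plate chondrocytes (100% ± 0), the cartilage proteoglycan Acan (98.1% ± 2.70), Comp (98.0% ± 2.81) and Nkx3-2 (84.6% ± 4.63, SD, n = 2). Bglap, Col10a1 and Col9a1 had no peak at their promoters. Of 21 genes of skeletal muscle 10 were marked (47.6%; adjusted p = 0.00278, Fisher's exact test), among them the actin Acta1 (100% ± 0), the myogenic factor Myod1 (99.2% ± 1.06), Des (99.2% ± 0.831) and Pax7 (97.4% ± 3.69, SD, n = 2). Actc1, Mef2c and Myh3 had no peak at their promoters. Of 21 surface ectoderm genes 17 were marked (81.0%; adjusted p = 1.17e-09, Fisher's exact test), including Tfap2a (97.1% ± 0.442), Cdh1 (96.5% ± 1.11), Sp8 (96.2% ± 2.62) and Tfap2c (95.3% ± 2.25, SD, n = 2). At the start of its lowest-numbered transcript Tfap2a was covered to 25.3% on average. The keratins Krt5 and Krt14 and the epidermal regulator Trp63 had no peak at their promoters. The skeletal call was lost with a window of 1 kb on each side, where 32.0% were marked (adjusted p = 0.0713, Fisher's exact test).

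For 4 further lists the call depended on the settings. Endothelial genes were marked in 6 of 15 cases (adjusted p = 0.0401, Fisher's exact test), with Esam and Sox18 at 100% ± 0 (SD, n = 2) and Cdh5, Egfl7 and Emcn without a promoter peak. Genes of Schwann cells and neural crest were marked in 6 of 14 (adjusted exact p = 0.0321), including Foxd3 (97.4% ± 1.5) and Sox10 (95.7% ± 6.13, SD, n = 2), while Cdh19, Mpz and Pmel had no peak at their promoters. At the most covered of its transcript starts Mpz reached 83.9%. Imprinted genes were marked in 8 of 21 (adjusted exact p = 0.0297), including Ascl2 (97.5% ± 1.70) and Kcnq1 (97.5% ± 3.61, SD, n = 2), with Igf2r, Magel2 and Mest without a promoter peak. Germline and pluripotency genes were marked in 9 of 24 (adjusted exact p = 0.0326), including Tdgf1 (98.2% ± 0.212) and Lin28a (92.8% ± 3.08, SD, n = 2), while Dazl, Dppa2 and Dppa4 had no peak at their promoters. Against random lists matched on promoter CpG content, the adjusted permutation p was 0.0831 for endothelium, 0.0831 for imprinted genes and 0.124 for the germline list. Against marks rotated along the gene order it was 0.0711 for the Schwann cell list. With either replicate list alone 35.7% of the Schwann cell list were marked (adjusted exact p = 0.0657 without replicate 1 and 0.0672 without replicate 2), and 25% of the germline list (adjusted p = 0.174 and 0.281).

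For a further 3 lists no difference from other genes was detected with the settings used. Blood and macrophage genes were marked in 6 of 20 (adjusted exact p = 0.160), led by Gata2 (98.4% ± 2.30) and Ikzf1 (97.1% ± 0, SD, n = 2), with C1qb, Cd68 and Csf1r without a promoter peak. Polycomb subunits and cell cycle inhibitors were marked in 5 of 23 (adjusted exact p = 0.582), the highest being the inhibitors Cdkn2a (94.9% ± 1.18) and Cdkn2b (88.2% ± 2.83, SD, n = 2). Terminal products of other organs were marked in 4 of 34 (adjusted exact p = 0.528), among them Mbp (93.6% ± 6.24) and Aqp2 (62.3% ± 9.83, SD, n = 2), whereas Alb, Apoa1 and Cyp2e1 had no peak at their promoters. The blood list passed with windows of 5 kb (35%, adjusted exact p = 0.0304), with any overlap counted (45%, 0.0440) and against lists matched on CpG (11.7% marked, adjusted permutation p = 0.0494). The direction turned for terminal products with any overlap (29.4%, adjusted exact p = 0.424) and with 1 kb windows (20.6%, 0.523), and for the polycomb list at 50% coverage (8.70%, 0.760). None of the 32 housekeeping genes was marked, fewer than among other genes (adjusted p = 0.00615, Fisher's exact test). With the list of replicate 2 alone 3.12% of them were marked and the adjusted p was 0.105.

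**Figure D3:**
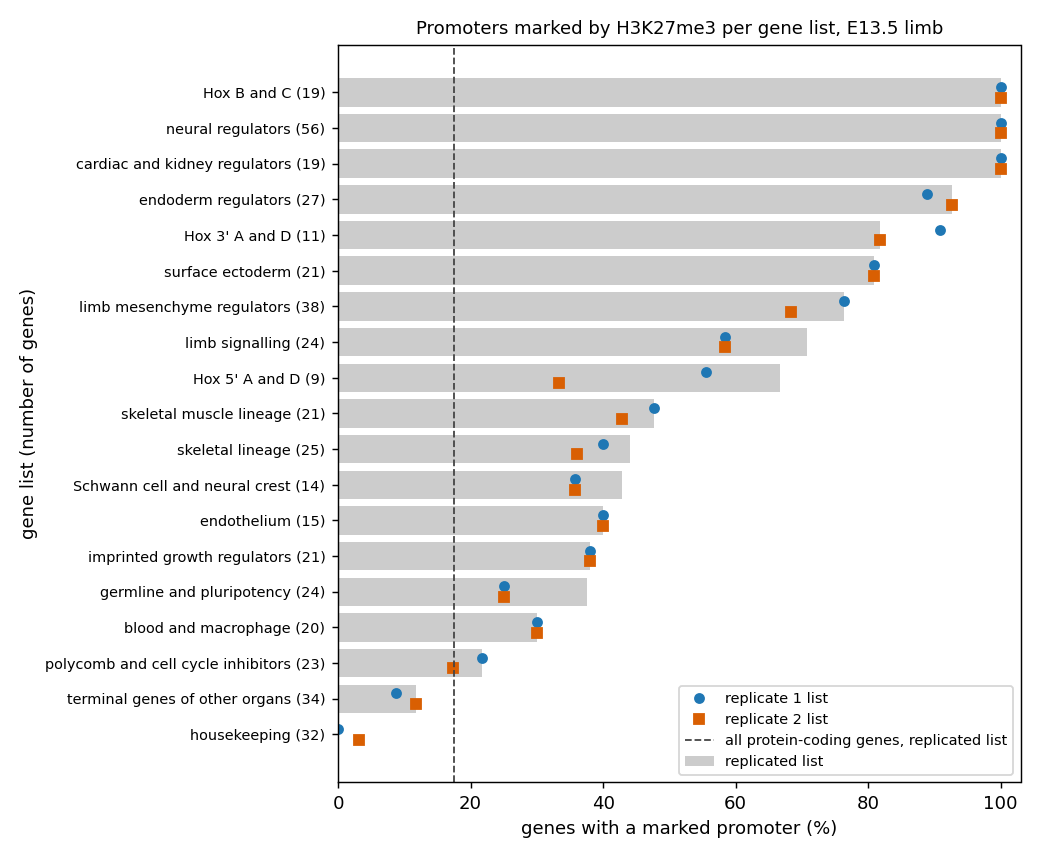
Share of the genes in each fixed list (y axis, number of genes in parentheses) whose promoter was marked (x axis, %), in the replicated list (bars), the replicate 1 list (circles) and the replicate 2 list (squares); the dashed line is the share among all protein-coding genes, 17.5%. The nervous system, heart and kidney, and HoxB and HoxC lists reach 100%, and the housekeeping bar is at 0.

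Gene families were defined by symbol. Every member was marked in the Pax (9), LIM homeobox (12), Irx (6), Nkx (14) and Dlx (6) families, with adjusted p over the 20 families from 6.87e-11 to 3.77e-05 (Fisher's exact test). Homeobox genes of the Hox family were marked in 34 of 39 (adjusted p = 2.30e-20), Wnt ligands in 17 of 19 (5.05e-11), Gata factors in 5 of 6 (0.000875), Fgf ligands in 16 of 22 (3.72e-08), Sox factors in 13 of 19 (2.17e-06), Tbx factors in 9 of 13 (6.78e-05), Fox factors in 26 of 44 (1.76e-09) and Bmp and Gdf ligands in 11 of 21 (0.000335), all by Fisher's exact test. For the clustered Hox genes the adjusted permutation p against rotated marks was 0.000500. In each replicate list 54.5% of the Fgf ligands and 42.9% of the Bmp and Gdf ligands were marked. Wnt1, Wnt7b and Fgf3 were covered to 100% ± 0 (SD, n = 2), while Wnt5a was at 5.24% ± 0.0884 and Wnt5b at 9.46% ± 6.77 (SD, n = 2), or 28.4% at the start of its lowest-numbered transcript. Voltage-gated potassium channels were marked in 28 of 30 (adjusted p = 8.35e-19, Fisher's exact test), with Kcnc4, Kcnc1 and Kcnq2 at 100% ± 0 (SD, n = 2) and Kcna10 and Kcnd1 without a promoter peak.

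Other families were marked less often than the remaining genes. Olfactory receptors were marked in 3 of 1093 (adjusted p = 1.59e-86), vomeronasal receptors in 0 of 327 (6.07e-27), Zfp zinc finger genes in 19 of 365 (1.01e-11), ribosomal protein genes in 1 of 76 (1.93e-05) and keratin-associated protein genes in 1 of 57 (0.000396), all by Fisher's exact test. Random lists matched on promoter CpG had 2.30% marked for olfactory receptors and 2.35% for vomeronasal receptors, against 18.4% and 17.7% of other genes. Much of the gap for these 2 families thus went with low promoter CpG. The adjusted permutation p against the matched lists was 0.000308 and 0.00200. Matched lists had 20.2% marked for Zfp genes and 23.8% for ribosomal protein genes. For keratin-associated proteins they had 7.90% marked, and the adjusted permutation p was 0.0956. For clustered protocadherins, marked in 7 of 57 (12.3%), no difference from other genes was detected (adjusted p = 0.383, Fisher's exact test). Their matched lists had 23.6% marked (adjusted permutation p = 0.0541). With the list of replicate 2 alone, 5.26% of the protocadherins were marked, fewer than among other genes (adjusted p = 0.0394, Fisher's exact test). The marked ribosomal protein gene was Rpl3 (97.5% ± 2.99, SD, n = 2). Its annotated 5' end is that of an upstream transcript, and at the start of its lowest-numbered transcript the replicated list covered 0% of the window.

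Promoters rich in CpG dinucleotides were marked more often. In the 5 deciles of highest CpG observed/expected ratio 2540 of 10877 promoters were marked (23.4%), against 1259 of 10878 (11.6%) in the 5 lowest (odds ratio 2.33, p = 1.11e-117, Fisher's exact test, two-sided, which treats neighbouring genes as independent). The share rose from 0.597% in decile 1 to 27.1% in decile 5 and lay between 20.8% and 24.6% in deciles 6 to 10. In the replicate lists the share in decile 5 was 23.5% ± 1.30 and in decile 1 it was 0.391% ± 0.0325 (SD, n = 2).

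**Figure D4:**
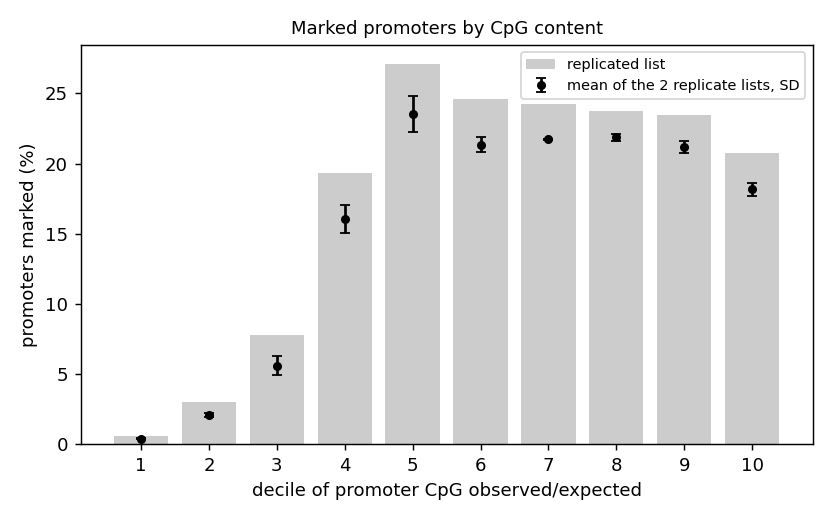
Share of promoters marked (y axis, %) per decile of promoter CpG observed/expected (x axis); bars are the replicated list, and points with error bars the mean and SD of the 2 replicate lists. Bars climb from 0.597% in decile 1 to 27.1% in decile 5 and then stay between 20.8% and 24.6%.

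Over the genome, promoter sequence held 18.0% of the bases covered by the replicated list but 3.16% of the genome, a ratio of 5.68 (two-sided permutation p = 0.002, the smallest that 1000 circular shifts can give). The ratio was 1.75 in exons and 0.695 in intergenic sequence, with the same p. In the replicate lists it was 6.02 ± 0.706 for promoters, 1.81 ± 0.112 for exons and 0.682 ± 0.0353 for intergenic sequence (SD, n = 2). Introns had a ratio of 0.943 (permutation p = 0.0200), but 0.993 (permutation p = 0.756) when peak summits were counted in place of bases.

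The replicates differed on the X chromosome. Replicate 1 covered 1.37% of X, against a mean of 2.21% over the autosomes (SD between autosomes 0.703), and replicate 2 covered 2.66% of X against 1.64% (SD between autosomes 0.576). The ratio of X to autosomes was thus 0.619 in replicate 1, where X ranked 18 among 20 chromosomes, and 1.62 in replicate 2, where it ranked 2. In the replicated list the ratio was 1.36 and X ranked 4 (exact one-sided rank p = 0.2, with 0.05 the smallest the number of chromosomes allows). The 5 promoters with the largest excess in replicate 2 were all on X. They were those of Sh3kbp1 (14.1% in replicate 1 and 74.7% in replicate 2), Mcf2 (22.4% and 77.7%), Zfp185 (1.83% and 53.6%), Maged1 (0% and 51.6%) and Tspyl2 (18.7% and 69.2%). At the start of its lowest-numbered transcript Mcf2 had no coverage in either replicate. No autosomal promoter differed by 50 percentage points or more. The 5 with the largest excess in replicate 1 were the autosomal Phyhip, Stxbp2, Rab39, Pik3ap1 and Nxph3, with differences from -36.8 to -41.1 percentage points.

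**Figure D5:**
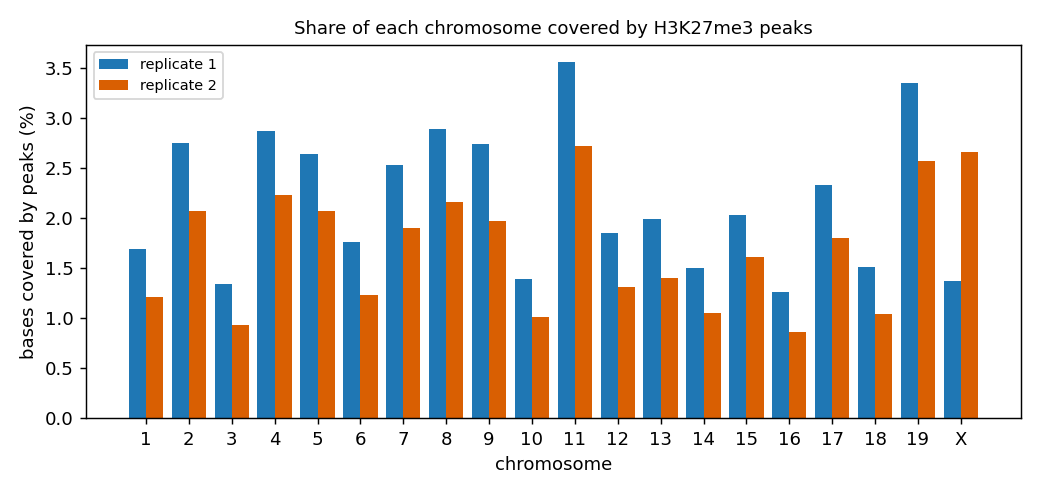
Share of each chromosome's bases covered by peaks (y axis, %) in replicate 1 (left bar of each pair) and replicate 2 (right bar), for chromosomes 1 to 19 and X (x axis). Replicate 1 is higher on each autosome, and on X replicate 2 covers 2.66% against 1.37%.

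Merging replicated peaks over gaps of at most 3 kb gave 22470 domains with a median width of 1377 bp. Of these, 2269 spanned at least 10 kb, held 52.4% of all domain bases and contained the 5' ends of 1255 protein-coding genes. A protein-coding 5' end lay in 45.7% of them. The broadest domain, 285 kb on chromosome 8 (91766710 to 92052093), held the start of Irx3 and was followed by the 232 kb domain over HoxC (chromosome 15, 102894796 to 103126706). Next came 221 kb at Pax2 (chromosome 19, 44626496 to 44847541), 195 kb over most of HoxB (chromosome 11, 96246578 to 96441550) and 192 kb at Dio3, which encodes a thyroid hormone deiodinase (chromosome 12, 110111228 to 110302902). Cdh22 and 1700025C18Rik shared a domain of 188 kb, Foxd2, Foxe3 and Gm12830 one of 137 kb, Rhcg one of 133 kb, Grik3 one of 130 kb, and HoxD with Evx2 and Gm28230 one of 129 kb. Of the 15 broadest, 5 held no protein-coding 5' end, among them 158 kb on X (99475223 to 99632809), of which replicate 1 covered 27.7% and replicate 2 48.3%. Starts in domains of at least 10 kb were more frequent than among other genes for the nervous system list (54 of 56; adjusted p = 1.10e-63), the limb mesenchyme list (25 of 38; 8.44e-22) and the heart and kidney list (19 of 19; 1.21e-23), by Fisher's exact test. The number of broad domains was 1210 with a merging gap of 1 kb and 4285 in the pooled list.

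The highest deposited signal value in the replicated list, 17.4, belonged to a peak of 13.2 kb over Neurog3, an endocrine pancreas determinant (chromosome 10, 62124948 to 62138144). Among the 10 highest, peaks at Adra2c, Barhl1, Nrg3, Crmp1 and Kcnk9 also contained the gene's 5' end. The others lay 3902 bp from that of Vgf, 27687 bp from Polg, 42393 bp from Sptbn4 and 89345 bp from Engase. Starts of other transcripts were not used for these distances, and Sptbn4 was covered to 100% at the most covered of its transcript starts. Signal values were used only to rank peaks within a list.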

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

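All comparisons were recomputed under the alternatives, and the start of the lowest-numbered transcript, the restriction to autosomes, and the matched lists and rotated marks as alternatives for the families were added after seeing the data. Of 650 alternative values, 605 kept their direction and side of the threshold (or moved within the replicate spread, or by under 1.5 times for counts), and 41 of 58 comparisons did so in every alternative run. For the named genes 385 of 2072 alternative coverage values moved by more than the SD between replicates, which leaving out a replicate cannot do at n = 2. Most of these came from windows of 5 kb, the pooled list and windows of 1 kb, and coverage in 5 kb windows fell to 42.7% for Lin28a, 49.4% for Des and 52.8% for Tdgf1. The cause of the changes was not tested. The q filter removed 2.75% of the replicated peaks and is a weak test for that list. No paired analysis was possible because there is only 1 group. With n = 2 and unknown depth, weak peaks cannot be separated into real and false ones.

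Leaving out each replicate gave 33.3% to 55.6% of posterior HoxA and HoxD genes marked, 35.7% of the Schwann cell list, 25% of the germline list, 0% to 3.12% of housekeeping genes, 5.26% to 8.77% of protocadherins, 0 to 1 lists below other genes, and an X to autosome ratio from 0.619 to 1.62, which crosses 1. With the pooled list the call ended for endothelium (40%, adjusted exact p = 0.0594) and imprinted genes (38.1%, 0.0558), introns gave 0.978 (permutation p = 0.478) and broad domains numbered 4285. With 1 kb windows it ended for the skeletal (32%) and germline (29.2%) lists, terminal genes turned to 20.6% (above other genes, adjusted exact p = 0.523), and the promoters common to both replicates were 84.1%. With 5 kb windows the germline (29.2%) and Schwann cell (28.6%) calls ended and the blood list passed (35%, adjusted exact p = 0.0304). Counting any overlap, the blood list passed (45%), the germline (41.7%) and imprinted (42.9%) calls ended, terminal genes turned to 29.4% (adjusted exact p = 0.424) and common promoters fell to 75.7%. At 50% coverage the calls ended for posterior HoxA and HoxD genes (22.2%) and the germline list (25%), and the polycomb list turned to 8.7% (adjusted exact p = 0.76). With any transcript start they ended for endothelium (40%), germline (37.5%) and imprinted genes (38.1%), and with the lowest-numbered transcript for the Schwann cell (35.7%) and imprinted (33.3%) lists. Random lists matched on CpG had 18.1% marked for endothelium, 21.6% for germline, 19.2% for imprinted genes and 7.90% for keratin-associated proteins (adjusted permutation p = 0.0956), whose calls ended, 11.7% for blood, which passed (adjusted permutation p = 0.0494), and 11.6% for terminal genes, which then lay above it (adjusted p = 1). Rotated marks gave 17.6% for endothelium, 17.7% for Schwann cells and 17.5% for imprinted genes, whose calls ended. Introns at peak summits gave 0.993 (permutation p = 0.756), a merging gap of 1 kb gave 1210 broad domains and a width of 5 kb gave 5243.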

Other observations

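The gene sets, the non-coding genes and the test of peak numbers in this part were chosen after the results were seen. So were the comparisons of X with replicate 1 and without the bins with most extra bases. The other 3 tests of X and the CpG test of channel and receptor genes were fixed before their results. Genes for neurotransmitter receptors were examined together with those for calcium and sodium channel pore subunits, and the receptor genes were widely marked. Of the 113 receptor and channel genes 74 were marked (65.5%; p = 1.08e-29, Fisher's exact test), and the shares in the replicate lists averaged 64.2% ± 0.626 (SD, n = 2). Some of these genes share a domain, such as Gabrb1 and Gabra4 (3.41 kb), and rotated marks were not used for these sets. All 8 metabotropic glutamate receptors were marked, 27 of 33 monoamine and muscarinic receptors, 14 of 18 ionotropic glutamate receptors, 11 of 19 GABA-A receptors and 7 of 16 nicotinic receptors (adjusted p = 2.01e-06, 8.24e-15, 1.27e-07, 0.000151 and 0.0181, Fisher's exact test). Grik3, Grin2c and Adra2c were covered to 100% ± 0 (SD, n = 2). The pore subunits of calcium channels (4 of 10, adjusted p = 0.0939) and sodium channels (3 of 9, adjusted p = 0.197) did not pass Fisher's exact test. Against lists matched on promoter CpG their one-sided permutation p was 0.152 and 0.229. Promoter CpG content does not account for the excess over the 113 genes together, since random lists matched on it had 19.9% marked (one-sided permutation p = 0.0001, the smallest 10000 lists can give). No biological explanation was tested.

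Promoters of long non-coding genes followed their neighbours. Of 158 lincRNA genes within 5 kb of a marked protein-coding 5' end 84.8% were marked, against 1.92% of the 469 that had unmarked ones nearby and 7.97% of the 4678 with none nearby; shared windows contribute to this. In the replicate lists these shares averaged 77.8% ± 1.79, 1.17% ± 0.452 and 6.05% ± 0.756 (SD, n = 2). For antisense genes the shares were 88.6%, 1.52% and 9.21%, and in the replicate lists 79.2% ± 2.77, 0.762% ± 0 and 7.35% ± 0.599 (SD, n = 2). In the Hox clusters Hotair was covered to 97.4% ± 3.71, Hotairm1 to 84.9% ± 1.40 and Hottip, at the 5' end of HoxA, to 31.3% ± 6.24 (SD, n = 2). Xist, H19, Malat1 and Tug1 had no peak at their promoters in either replicate.

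The X chromosome was covered 1.62 times as much as the autosomes in replicate 2 and 0.619 times in replicate 1. With the 84994 strongest peaks of each list the quotient of these ratios was 2.89, against 2.61 with all peaks, which argues against unequal peak numbers. The 18 bins of 1 Mb with most extra bases in replicate 2 held 63.3% of them. This met the rule fixed beforehand for a few regions of X as the cause. That rule separates poorly, since the densest 18 bins also held 64.2% of the replicate 1 bases on X. Without the 18 bins with most extra bases the quotient, computed after the results were seen, was still 2.58. This argues against a few regions as the whole cause. Of the bases on X covered in replicate 2 alone 53.0% lay in genes, above all 1000 shifted lists (highest 50.2%), which met the rule fixed beforehand. Of those covered in replicate 1 alone 50.3% lay in genes. This was above the 95th percentile of their shifts (37.7%) and just under the highest (50.4%). Because bases of replicate 1 alone lay in genes nearly as often, this test leaves added H3K27me3 over X genes open. Replicate 2 covered more than replicate 1, relative to autosomes, in 93.9% of the X bins with a peak (17.2% to 46.0% on single autosomes), as a different X dosage between a ChIP library and its control might give; that and a different sex balance of the embryos, which was not tested, cannot be told apart here because the control libraries were not analysed and the labels give mixed sexes.

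Among X promoters in the 5 upper CpG deciles, replicate 1 marked 23.3% and replicate 2 36.5%, against 21.0% and 20.2% on autosomes. In the 5 lower deciles, which hold 660 of the X genes, replicate 1 marked 5.61% and replicate 2 10.9%, against 10.2% and 8.97% on autosomes. Kdm6a, Kdm5c, Eif2s3x, Ddx3x and Pbdc1, X genes known to escape inactivation, had no peak at their promoters in either replicate. They lie in the upper CpG deciles, where most X promoters were unmarked in each replicate, so these 5 genes alone show no link with escape.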
